A study of Homo sapiens with 2 samples.

How the data were processed

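Gene expression was measured in KG1a cells, a human acute myeloid leukemia line that grows as undifferentiated myeloblasts, with Affymetrix arrays. The design had 2 samples, 1 of cells in which LKB1 (gene symbol STK11, a serine/threonine kinase that activates AMPK and its relatives) was knocked down with an shRNA and 1 of negative control cells, so each group held 1 array. Per the labels' protocols, cells were grown in medium with 10% serum, total RNA was extracted with Trizol, and biotinylated cRNA was made from 6 ug of total RNA by the standard Affymetrix protocol. The software, background correction, probe set summary and between-array normalization are not given in the sources used here.

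The deposited table held 1 log2 value per probe set and array for 49395 probe sets. The authors had centred every probe set on the mean of its 2 arrays: the 2 values of all 49395 probe sets summed to 0 within 1e-06, and both columns had a median of 0. The difference between the arrays was therefore kept and the signal level was lost, apart from a coarse limit for some probe sets that the spacing of the values gives. No probe set could be ranked by brightness or called detected from the table, and for arrays the number of arrays limits the precision. The base of the logarithm is not stated. It was taken as 2, because the spacing of the values fits single-precision numbers of the size of log2 array signals, which does not exclude a natural logarithm. All folds below are 2 raised to the absolute difference.

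Probe sets were named through the array's annotation. Of the 49395 probe sets, 45278 had 1 gene symbol, 1333 had several, 2682 had no gene listed and 102 were Affymetrix controls. The single-gene probe sets stood for 18244 genes, and 45208 of them were matched to the current RefSeq gene table by gene identifier, with no change of symbol. Some list members were not analysed here because no single-gene probe set named them.

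The plan fixed before the data were examined represented a gene by its brightest probe set, kept genes above the median brightness, and matched random lists on mean expression in 20 bins. None of these steps could be computed from centred values. A gene's value was instead the mean over all its single-gene probe sets of the log2 difference, knockdown minus control, which the plan held as an alternative, with the standard deviation between probe sets as its error. That error describes agreement within 1 pair of arrays. Probe sets of a gene can share probes, and the error holds no variation between cultures. No brightness limit was applied. The planned quantile normalization, loess correction, brightness limits, floor and pseudocount were not run for the same reason.

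No test between the groups was possible with 1 array each, and no p-value between groups is given. Genes were counted by size, at 2-fold with 1.5-fold and 3-fold as alternatives. Counts of list members at 1.2-fold were added after the data were seen. For each of 42 gene lists fixed before the data were examined, the median difference of the measured members was set against the medians of 10000 random lists of the same size, matched on the number of probe sets per gene (1 to 5, and 6 or more). A list was called apart in the lowest or the highest 2.5% of the random medians. These percentiles describe the 2 arrays, and genes of a list are not independent. If they were, 2.1 of the 42 lists would be apart by chance. The 95% interval of a list's median came from 2000 bootstrap draws of its members. The procedure was tested on simulated lists of 20 genes drawn from the 18244 genes. With no added shift 2.5% of 200 lists passed the upper limit. With a shift of 0.1 67.0% did, and with a shift of 0.2 100% did. These lists and the random lists came from the same genes, so the share without a shift was set by the limit itself. The simulation held independent genes and does not give how often lists of co-regulated genes are called.

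The genes named in the text follow a rule: STK11, then the 12 genes with the largest positive and the 12 with the largest negative difference among those whose probe sets all differed in the same direction, then up to 4 members of each list with the largest absolute difference. Genes outside the rule are marked as chosen after their values were seen.

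Alternatives added after the data were seen used the median of a gene's probe sets, left out probe sets whose names end in _x_at or _s_at (Affymetrix's marks for probes shared with other transcripts), kept only genes with 2 or more probe sets, left out the highest probe set of each such gene (for lists), centred the differences on the hybridisation spikes, or left out 5517 single-gene probe sets with the finest value spacing. That spacing is the step of single-precision numbers under 4, so these probe sets had a signal under 4 on the authors' log scale on at least 1 array. A signal under 4 can also give values on a coarser step, so not all such probe sets were left out. The finest spacing was found in 12 of 43 tag, trp and background control probe sets. Among control probe sets for the hybridisation spikes, GAPDH, actin and ribosomal RNA it was found in 0 of 30. The 24 probe sets for a second kind of spike, the poly-A spikes, were not part of this count. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.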

Results

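The study asked which genes differ when LKB1 is lowered in KG1a leukemia cells, with leukemic stem cell properties as its stated interest. It compared 1 array of LKB1 knockdown cells with 1 array of negative control cells. Every difference below is the knockdown array minus the control array on the log2 scale, has no replicate check, and carries as its error the standard deviation (SD) between the probe sets of a gene. Over 18244 genes the median difference was 0.02, and 53.9% of genes were higher in the knockdown array. The middle 90% of genes lay between -0.24 and 0.29. Among genes with 2 or more probe sets, the median SD between them was 0.12.

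STK11, which encodes LKB1, was lower in the knockdown array, in the direction of the labels. Its 1 single-gene probe set differed by -0.38, which left 76.6% of the control signal. Of the 6419 genes with 1 probe set, 88 were as low or lower. The LKB1 complex list, STK11 included, was not called, with a median of -0.12 at percentile 6.18 over 5 genes. STRADB, which encodes a pseudokinase partner of LKB1, was at -0.45 with 1 probe set, and STRADA, its relative, was at -0.12 ± 0.07 (SD, 3 probe sets). The scaffold gene CAB39L was at 0.10, and below 0 when differences were centred on the hybridisation spikes. Centring on the poly-A spikes, at 0.06, would leave it above 0. The STK11 value rests on a probe set of the kind that can share probes with other transcripts.

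Control probe sets also differed between the arrays. The 3 probe sets for 18S ribosomal RNA were higher in the knockdown array by 0.46 ± 0.07 and the 3 for 28S ribosomal RNA by 0.37 ± 0.06 (SD over probe sets). The 18 probe sets for the hybridisation spikes, added in known amounts before hybridisation, were higher by 0.11 ± 0.07. The 24 probe sets for the poly-A spikes were higher by 0.06 ± 0.11 on average, with 18 of them above 0. Scaling the arrays to the hybridisation spikes would lower every difference by 0.11. That changes how many genes lie above 0 but not the percentile of a list. The 3' minus 5' difference, a measure of RNA integrity, moved by -0.02 for GAPDH and by 0.14 for ACTB. The 23 background probe sets followed their GC count, from -0.21 at a count of 3 to 0.29 at a count of 24, with a Spearman rho of 0.94 across probe sets. Those with counts of 3 to 9 averaged -0.07, those with 10 to 15 averaged -0.002 and those with 16 to 25 averaged 0.17. Whether a GC-dependent reading shifts the gene lists below, the lower as well as the higher ones, was not tested on their probe sets.

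**Figure D1:**
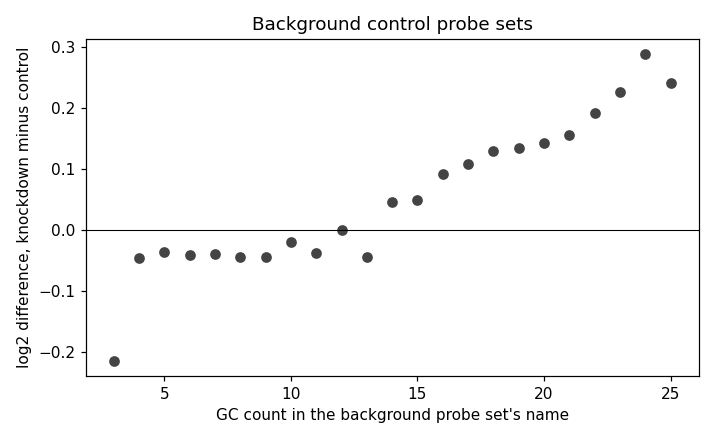
Log2 difference, knockdown minus control (vertical axis), of each background control probe set against the GC count in its name (horizontal axis); each of the 23 points is 1 probe set. The differences run from -0.21 at a GC count of 3 to 0.29 at a GC count of 24.

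Few genes differed strongly. At 2-fold or more, 3 genes were higher and 3 were lower, and at 1.5-fold or more, 52 were higher and 28 were lower. The 3 higher genes were GZMB, the serine protease granzyme B of cytotoxic lymphocyte granules, at 1.62 with 1 probe set (3.08-fold), MUC13, a transmembrane mucin, at 1.60 ± 0.22 with 2 probe sets (3.03-fold), and HPSE, the heparan sulfate-cleaving enzyme heparanase, at 1.04 ± 0.44 with 2 probe sets (2.05-fold). The 3 lower genes were FOXN2, a forkhead transcription factor, at -1.43 ± 1.82 with 2 probe sets, APP, the amyloid precursor protein, at -1.30 ± 0.52 with 13 probe sets, and TNKS2, a tankyrase, at -1.05 ± 1.48 with 4 probe sets. APP was named because of this count, since 1 of its 13 probe sets was at 0.27 while the others lay between -1.67 and -0.96. FOXN2 and TNKS2 each rest on 1 probe set, at -2.72 and -3.25. With the probe sets of finest spacing left out, FOXN2 was at -0.15 and TNKS2 at -0.32, and the count of lower genes was 1.

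The other genes at the upper end included S100P, a calcium-binding protein, at 0.99, and GZMA, granzyme A, at 0.89, each with 1 probe set. AGMO, an ether lipid-cleaving monooxygenase, was at 0.89 ± 0.05 with 2 probe sets, IL21R, the interleukin-21 receptor, at 0.80 ± 0.08 with 2, and ABLIM1, an actin-binding protein, at 0.81 ± 0.28 with 4. ISG20, an interferon-induced exonuclease, PCED1B and the small nucleolar RNA SNORA28 were at 0.81, 0.78 and 0.80 with 1 probe set each. HSPD1, a mitochondrial chaperonin, had a mean of 0.92 ± 1.29 over 8 probe sets that rests on 2 probe sets at 2.98 and 3.03, and the median of its probe sets was 0.28. At the lower end, LMNB1, which encodes the nuclear lamina protein lamin B1, was at -0.86 ± 0.15 with 4 probe sets. MSI2, an RNA-binding protein of hematopoietic stem cells, was at -0.86 ± 0.49 with 5. SLC5A12, a lactate transporter, was at -0.71 ± 0.31 with 4, and MAPK8, the stress kinase JNK1, at -0.72 ± 0.74 with 3, of which 1 was at -1.56 and the median at -0.45. CCDC71, ZNF415, MORN2, C5orf23, POM121C and FAM200C had 1 probe set each and lay between -0.87 and -0.70.

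**Figure D2:**
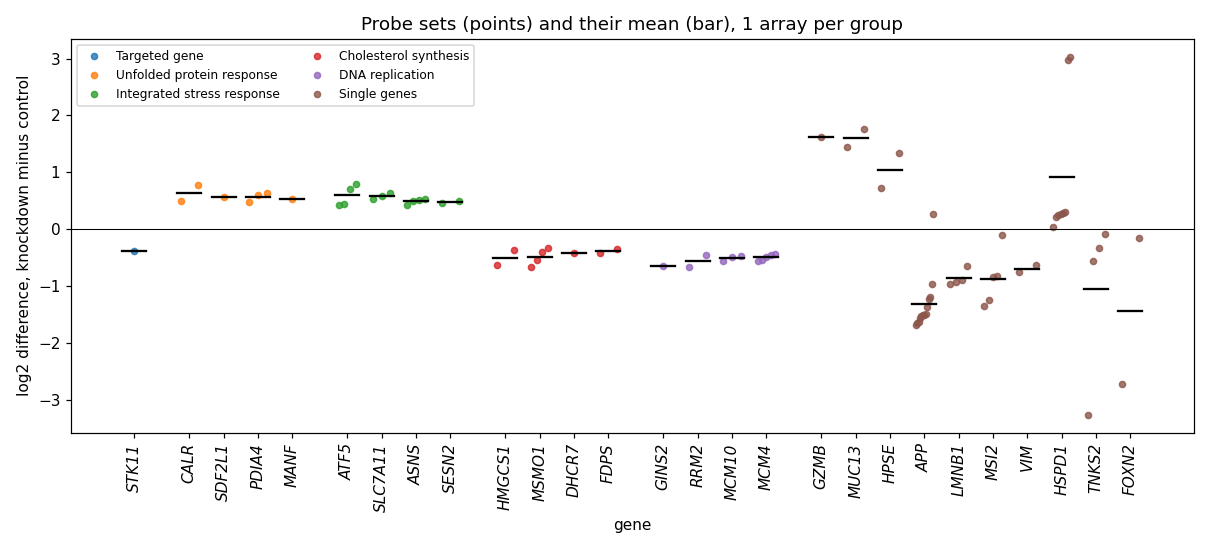
Log2 difference, knockdown minus control (vertical axis), for named genes (horizontal axis, coloured by group); each point is 1 probe set and each black bar is the mean over the gene's probe sets, with 1 array per group. Probe sets of the stress genes lie above 0 and those of the cholesterol and replication genes below 0, while HSPD1, TNKS2 and FOXN2 each hold probe sets far from the others.

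Genes of protein folding and stress adaptation were higher in the knockdown array. The unfolded protein response list, of genes induced by misfolded protein in the endoplasmic reticulum, had the highest median of the 42 lists, at 0.38 with a 95% bootstrap interval of 0.23 to 0.49. All 18 measured members were above 0 and 12 were at least 1.2-fold higher. Among them were CALR, the calcium-binding chaperone calreticulin, at 0.64 ± 0.20, PDIA4, a disulfide isomerase, at 0.57 ± 0.08, SDF2L1 at 0.58 and MANF at 0.54. The integrated stress response and amino acid synthesis list had a median of 0.25, with 19 of 22 members above 0 and 10 at least 1.2-fold higher. ATF5, a stress-induced transcription factor, was at 0.60 ± 0.19, SLC7A11, the cystine importer, at 0.59 ± 0.06, ASNS, asparagine synthetase, at 0.50 ± 0.05 and SESN2, a leucine sensor that restrains mTORC1, at 0.48 ± 0.03. All 12 heat shock genes were above 0, with a median of 0.27. Their leading members included the cytosolic co-chaperones DNAJA1 at 0.47 ± 0.08 and BAG3 at 0.40, but also HSPD1 and HSPE1, which act in mitochondria, with HSPE1 at 0.38 ± 0.04. Each of these 3 medians was above at least 99.9% of random lists. The T and NK cell list and the stromal and endothelial list were also higher, with medians of 0.12 and 0.16. Besides GZMB and GZMA, the T cell genes CD3D and LCK led the former, at 0.49 ± 0.04 with 2 probe sets and 0.24 ± 0.09 with 5.

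Antioxidant genes were split. The NRF2 list had a median of 0.05 at percentile 76.2, and 6 of its 15 members were at least 1.2-fold higher while none was 1.2-fold lower. HMOX1, heme oxygenase 1, was at 0.70 ± 0.01 with 3 probe sets, NQO1, a quinone reductase, at 0.69 ± 0.17 with 2, and GCLM, a subunit of the enzyme that limits glutathione synthesis, at 0.58 ± 0.05 with 2. With the probe sets of finest spacing left out, this list stood at percentile 98.9.

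Cholesterol synthesis genes were lower in the knockdown array. Their median of -0.26 (95% bootstrap interval -0.37 to -0.16) was the lowest of the 42 lists, and 18 of 19 measured members were below 0, with 8 at least 1.2-fold lower. HMGCS1, which makes the HMG-CoA of the mevalonate pathway, was at -0.49 ± 0.19, MSMO1 at -0.48 ± 0.14, DHCR7, which catalyses the last step to cholesterol, at -0.42, and FDPS, farnesyl diphosphate synthase, at -0.38 ± 0.05. Fatty acid synthesis genes were not called, with a median of 0.03 at percentile 60.4. Fatty acid oxidation, glycolysis and hypoxia-responsive genes were not called either, with medians of -0.05, 0.04 and 0.03. Oxidative phosphorylation genes were slightly lower, with a median of -0.07 at percentile 0.51, and 10 of 33 members were above 0. This call was lost when the highest probe set of each gene was left out, in the random lists as well, at percentile 7.74. SDHA, a subunit of succinate dehydrogenase, was at -0.24 ± 0.06.

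Proliferation genes were lower in the knockdown array. Of 23 G1/S and DNA replication genes, 19 were below 0 and 10 were at least 1.2-fold lower, with a median of -0.18. GINS2, a subunit of the replicative helicase, was at -0.64, RRM2, the regulated subunit of ribonucleotide reductase, at -0.55 ± 0.14, and MCM10, a replication initiation factor, and MCM4, a helicase subunit, were at -0.50 ± 0.05 and -0.49 ± 0.06. Of 25 G2/M genes, 21 were below 0, with a median of -0.14. AURKB, a mitotic kinase, was at -0.48 and MKI67, the proliferation antigen Ki-67, at -0.42 ± 0.26. The medians of both lists were below all 10000 random medians. MYC target genes and cytosolic ribosomal protein genes were not called, with medians of 0.013 and -0.003. CDKN1A, the cell cycle inhibitor p21, was at 0.36 ± 0.12, and CDKN1B, its relative p27, at -0.28 ± 0.21. The p53 target list as a whole was at 0.05, percentile 75.9.

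Genes close to the LKB1 pathway gave small differences. AMPK subunits and AMPK-related kinases were not called, with a median of 0.003 and 10 of 19 members above 0. NUAK2 and MARK4, kinases that LKB1 phosphorylates, were at 0.37 and 0.35 with 1 probe set each, and PRKAA1, an AMPK catalytic subunit, at -0.25 ± 0.15 with 4. The list of CREB and CRTC targets, with the CRTC coactivators, had a median of 0.16 at percentile 99.98, with 14 of 18 members above 0 and 3 at least 1.2-fold higher. Without _x_at and _s_at probe sets its distance from the median of all genes fell from 0.141 to 0.078, at percentile 97.51, barely past the limit. PDE4B, a cAMP phosphodiesterase, was at 0.48 ± 0.30, and FOS, an immediate early transcription factor, at 0.25 ± 0.08. FOS and ATF3 are among the members that this list shares with the immediate early list, which was also called higher. The calls of these lists are therefore not separate evidence. The stromal and endothelial marker list had the same rounded median, 0.16. Regulators of mTOR were not called, with a median of -0.04. Within that list DDIT4, an mTORC1 inhibitor, was at 0.49 with 1 probe set, DEPTOR, an mTOR-binding inhibitor, at -0.44 ± 0.04 and RICTOR, the defining subunit of mTORC2, at -0.38 ± 0.12.

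Stem cell lists lay on both sides of the random lists. Stem cell transcription factors and self-renewal regulators were lower, with a median of -0.09 at percentile 0.27 and 16 of 22 members below 0. MSI2 led this list. GATA2, PBX3 and ERG, transcription factors of hematopoietic progenitors, were at -0.29 ± 0.29, -0.28 ± 0.16 and -0.26 ± 0.20. Leukemic stem cell surface markers had a median of 0.09 at percentile 98.5, with 15 of 22 members above 0. Centring on the hybridisation spikes would bring this median below 0 and leave its percentile. Centring on the poly-A spikes, at 0.06, would leave it above 0. ADGRG1, an adhesion receptor, was at 0.30 ± 0.21, IL1RAP, the interleukin-1 receptor accessory protein, at 0.30 ± 0.13 and CD9, a tetraspanin, at -0.26 ± 0.24. The call of the surface markers was lost without matching of the random lists, at percentile 96.3, and without the probe sets of finest spacing, at percentile 96.1. The B cell and the erythroid lists had medians of 0.09 and 0.10. The LSC17 score genes were not called, with a median of 0.07 at percentile 87.1, nor were Wnt pathway genes and ABC drug transporters, with medians of -0.002 and 0.052.

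**Figure D3:**
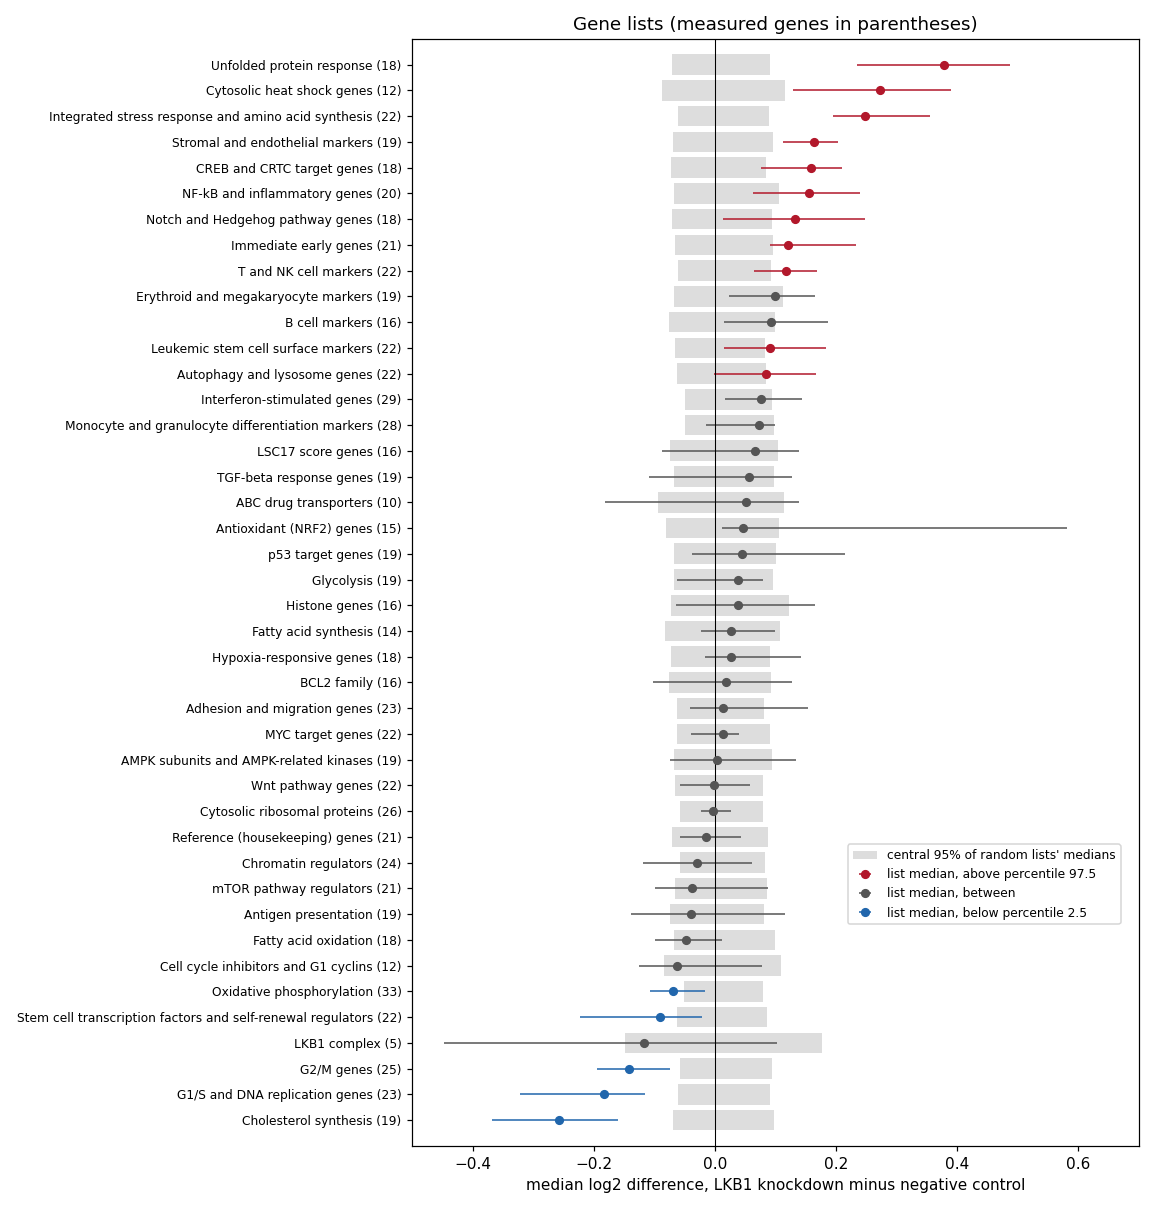
Median log2 difference, knockdown minus control (horizontal axis), of each of the 42 gene lists (vertical axis, measured genes in parentheses); points are medians, lines their 95% bootstrap intervals, and grey bars the central 95% of the medians of random lists. The unfolded protein response list lies highest at 0.38 and the cholesterol synthesis list lowest at -0.26.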

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

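The tests in this part were chosen after the values were seen, except the comparison of probe sets by spacing, whose outcome was unknown when its prediction was written.

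Some signals outside the gene values were higher in the knockdown array than in the control array. The probe set 11744080_x_at, listed for PRSS3P2, PRSS1 and PRSS2, was at 1.84, and 11744079_s_at, listed for PRSS2 and PRSS3, was at 1.69, both for trypsinogens. The probe set 11755243_a_at, with no gene listed, was at 1.16. The mean of the 18S ribosomal RNA probe sets was 0.46 and that of the 28S ribosomal RNA probe sets was 0.37. Other control probe sets were lower, among them the 3 for GAPDH, at -0.07, -0.07 and -0.04, and the 5' probe set for ACTB, at -0.13.

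Of the 5 lists of genes that mark other cell types, 2 were called higher in the knockdown array, the stromal and endothelial list with a median of 0.16 and the T and NK cell list with one of 0.12. The monocyte, B cell and erythroid lists, with medians of 0.07, 0.09 and 0.10, were not called. Cells of another type in the knockdown culture cannot be told apart from the other explanations. The 5 medians lie within 0.092 of one another, but each list has members of both directions, and a high level in KG1a itself could hide a small share of added cells. A general upward reading of dim probe sets also stays open. The median of the single-gene probe sets of finest spacing was 0.057 above that of the others (95% bootstrap interval 0.053 to 0.067). This met the prediction written beforehand for that explanation. Leaving these probe sets out of the lists was not part of that prediction. It lowered 1 of the 5 lists, the erythroid one, from 0.083 to 0.044 above the median of all genes. The others rose, the stromal list from 0.147 to 0.162, the T and NK cell list from 0.101 to 0.116, the B cell list from 0.076 to 0.0996 and the monocyte list from 0.055 to 0.061. Part of these changes is the median of all genes, which itself fell from 0.017 to 0.012. Some lists also lost members, the monocyte list from 28 to 22 genes, with its own median at 0.073 before and 0.074 after. Dim probe sets above the limit that the spacing gives cannot be picked out of centred values. Some under it also stayed in, where their values fell on a coarser step. A higher reading of probes rich in G and C is in line with the data: over the 22 autosomes the median difference followed the density of coding genes, which stands in here for GC content, with chromosomes that are not independent samples (Spearman rho 0.70, two-sided permutation p = 0.0007, Pearson r 0.57, rho 0.65 without the 2 chromosomes farthest from the median density). The chromosome medians ran only from -0.017 to 0.043, which does not give the size of such a reading in these lists. That reading was not tested on the probe sets of these lists. A change in the cells caused by the knockdown stays untested with 1 array per group. Among other lists with small upward medians, the distance of the CREB and CRTC targets from the median of all genes rose from 0.141 to 0.159 without the finest spacing. It fell to 0.078 without _x_at and _s_at probe sets. The same distance of the stem cell surface markers fell from 0.074 to 0.063 without the finest spacing.

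The unfolded protein response, integrated stress response and heat shock lists had medians of 0.38, 0.25 and 0.27. Probe sets with the finest spacing made up only 3 of the 178 probe sets of these lists. This small number argues against them as the whole cause. Leaving them out could therefore change little, and the values without them add no further evidence. The lowest of the 3 medians was then 0.23, that of the heat shock list. Its lower bootstrap bound of 0.13 lies above the random lists' upper limit of 0.11. Dim probe sets above the limit that the spacing gives, and those under it with values on a coarser step, were not tested. A few stray probe sets are also argued against. In the 3 lists, in the order above, 61 of 66, 64 of 70 and 41 of 42 probe sets were above 0. A median moves little with a few stray values, so leaving probe sets out adds little to this. The highest probe set of each gene was left out over genes with 2 or more probe sets, in the random lists as well. This left 14, 17 and 8 genes, and 1 of the 2 high HSPD1 probe sets stayed in. The medians were then 0.28, 0.24 and 0.29. The lowest of their lower bootstrap bounds, 0.09 for the heat shock list, lies above the random lists' upper limit of 0.06. A higher reading of GC-rich probes cannot be told apart from a change in the cells here, because the composition of these probe sets is not used here; the highest background probe set was at 0.29. Whether the lower LKB1 or differences between the cultures at harvest brought the higher values stays untested, since 1 array per group does not separate them.

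GZMB and GZMA were higher by 1.62 and 0.89, each with 1 probe set. In the same T and NK cell list CD3D, a T cell receptor subunit, was at 0.49 ± 0.04 with 2 probe sets and LCK, a T cell kinase, at 0.24 ± 0.09 with 5, while 6 of the 22 members were below 0, down to -0.15. T or NK cells in the knockdown culture cannot be told apart from induction in KG1a cells. The 20 members other than GZMB and GZMA had a median of 0.11, under the 0.16 of the stromal list, but for most of the list's probe sets a high level in KG1a itself could hide added cells. No high level applies to the 11 of 62 with the finest spacing, of which 7 were higher, with a median of 0.10; they go both ways at a low signal, which decides neither way.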

How the results depend on the processing

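No paired analysis was possible because each group held 1 array, and no replicate could be left out. Of the 16 lists called apart, 13 were called under all 6 alternatives tried. Some of the called lists share members, so their calls are not separate. The list of Leukemic stem cell surface markers lost its call without probe sets of the finest spacing (0.063 above the median of all genes, percentile 96.1) and with random lists not matched on probe sets (0.074, percentile 96.3). The list of Autophagy and lysosome genes lost its call with unmatched random lists (0.068, percentile 95.1). The list of Oxidative phosphorylation lost its call without each gene's highest probe set (-0.048, percentile 7.74). The cause of these losses was not tested. CREB and CRTC target genes stayed barely past the limit without _x_at and _s_at probe sets (0.078, percentile 97.51). Antioxidant (NRF2) genes and B cell markers gained a call without the finest spacing (0.11 and 0.10), and LSC17 score genes gained one over genes with 2 or more probe sets (0.10) and without each gene's highest probe set (0.14). Of genes at least 2-fold higher there were 3, and 52 at 1.5-fold. Of genes at least 2-fold lower there were 3, with 28 at 1.5-fold, 0 at 3-fold and 1 without the finest spacing. Centring on the hybridisation spikes would lower every difference by 0.11 and leaves list percentiles as they are; centring on the median of non-control probe sets moves nothing. STK11 has no value without _x_at probe sets or among genes with 2 or more probe sets. Of 1002 values of named genes under an alternative, 5 had the other sign (RPS15A, TCF7L2, LRP6 and CAB39L), that of CAB39L under the spike centring, and 64 moved by more than the spread between probe sets. Many of the 1002 could not change, so these counts do not measure robustness. The 178 centred on the median of non-control probe sets had a shift of 0, and the 134 over genes with 2 or more probe sets repeat the main values. The median of 1 or 2 probe sets also equals their mean. Of the 64, 55 came from the spike centring, which shifts every gene alike, and the other 9 from leaving out _x_at and _s_at probe sets. For genes with 1 probe set the spread was taken as 0.117, the median SD among genes with 2 or more. The spike shift of 0.107 is smaller, so genes with 1 probe set could not count as moved under it. The planned quantile, loess, brightness, floor and pseudocount alternatives were not run, because levels were lost in the centring. The number of arrays, 1 per group, limits every value.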

Other observations

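Inflammatory and immediate early genes were also higher in the knockdown array. Of 20 NF-kB and inflammatory genes, 18 were above 0, with a median of 0.15. The chemokine gene CXCL2 was at 0.63, with the same value in its 2 probe sets, so no spread is known for it. CXCL8, another chemokine gene, was at 0.56 ± 0.07 (3 probe sets), and PTGS2, the inducible cyclooxygenase, at 0.47 ± 0.04. Immediate early genes had a median of 0.12, with JUN at 0.47 ± 0.13 and KLF6 at -0.31 ± 0.18. Notch and Hedgehog pathway genes had a median of 0.13 and autophagy and lysosome genes one of 0.09, with MAP1LC3B, an autophagosome protein, at 0.39 ± 0.12 and SQSTM1, an autophagy receptor, at 0.31 ± 0.08. All 4 lists were above the upper percentile limit for random lists. But the call of the autophagy and lysosome list was lost with unmatched random lists, at percentile 95.1. The 95% bootstrap interval of its median, -0.002 to 0.167, includes 0. Centring on the hybridisation spikes would bring that median below 0, while centring on the poly-A spikes, at 0.06, would leave it above 0. The T and NK cell and stromal lists lay at 0.12 and 0.16.

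Interferon-stimulated genes were not called (median 0.08, percentile 93.0), with ISG20 at 0.81, MX1 at 0.43 and ISG15 at 0.38. TGF-beta response, BCL2 family, adhesion, antigen presentation, histone and chromatin lists were not called, with medians of 0.06, 0.02, 0.01, -0.04, 0.04 and -0.03. Among their members VIM, the intermediate filament vimentin, was at -0.69 ± 0.09, ITGB7, an integrin subunit, at 0.49 ± 0.19, SKIL, a repressor of SMAD signalling, at 0.48 ± 0.06, PMAIP1, the pro-apoptotic NOXA, at 0.36 ± 0.06, IDH2 at -0.33 ± 0.22 and IDH1 at 0.30 ± 0.03. The cell cycle inhibitor and G1 cyclin list was at -0.06 and the reference gene list at -0.02. CTSG, the granule protease cathepsin G, was at 0.57, KLF1, an erythroid transcription factor, at 0.41, and ITGA2B, a platelet integrin, at -0.40 ± 0.03.

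Some genes had 1 or 2 probe sets that stood far from the rest. Of 29271 probe sets of genes with 3 or more, 12 lay at least 1 log2 unit from their gene's median, in 10 genes, and 2 of the 12 ended in _x_at against 19.4% of all. They included TNKS2 at -3.25 against a gene median of -0.44, 2 of RAD23B at -2.14 and -1.97 against -0.21, INPP4B at 1.65 against 0.02, and 2 of HSPD1 at 3.03 and 2.98 against 0.28, both made for the same transcript. RAD23B and INPP4B were named after their values were seen.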
